A study of Mus musculus with 10 samples.

How the data were processed

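RNA sequencing counts were compared between retinas of untreated mice aged 3 months, with 5 wild-type libraries and 5 libraries whose genotype label is B6.129S2-Il6tm1Kopf/J, an interleukin-6 knockout line. Per the labels' protocols, retinas were frozen after removal, total RNA was taken up in Trizol, and Illumina libraries were prepared. The labels give a C57BL/6 background for both groups and no litter, sex, date or batch. Libraries were grouped by the genotype label. The labels carry no replicate numbers, so W1 to W5 (wild type) and K1 to K5 (labelled knockout) are names in accession order that pair no libraries. The labels do not state that the libraries come from separate animals, so p-values measure the spread between these samples, which may be partly technical. K5 carries a second index sequence in its label that differs from that of the other libraries.

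The counts are whole numbers of reads per gene that the authors deposited in a single table of 36115 genes, with no normalization. Per the submitters' processing notes, the tools were bcl2fastq, FastQC, STAR 2.5.3a, featureCounts 1.15.2 and DESeq2 1.14, on the genome build GRCm38.p5. The handling of strand, of reads that match several places and of overlapping genes is not given in the sources used here. Counts of near-identical gene copies, of overlapping genes and of antisense genes are therefore uncertain. Per the file headers, the table also holds the authors' DESeq2 comparison of knockout over control. In it, the deposited mean over the 10 libraries is a signal of counts divided by size factors, and it was not used. The deposited log2 fold changes and the deposited p-values, unadjusted and adjusted, were used to count the authors' calls, to compare those calls and their directions with the calls made here, and to read the mark of significance. A deposited mark of significance equals an adjusted p under 0.05 with an absolute log2 fold change above 1 in all 36115 genes.

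Gene identifiers were matched to GENCODE release M21 on GRCm38, where 35980 were found and 135 were not, and 33862 had the same coordinates. Coordinates printed are those of the deposited table. A set of 25 symbols that spreadsheet software had turned into dates was repaired from the identifiers, and 77 genes share a symbol with another. Every gene had at least 1 read in some library. No pair of libraries differed by as little as sampling noise.

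Genes were kept with edgeR's filterByExpr (minimum count 10, minimum total count 15), which left 18965. Library sizes were scaled with TMM factors, which ran from 0.954 to 1.04. Differences were tested with edgeR's quasi-likelihood test (glmQLFit and glmQLFTest) with genotype as the only term. A gene was called when its Benjamini-Hochberg adjusted p was under 0.05, with no fold threshold. "edgeR adjusted p" stands for that value, and log2 fold changes are libraries labelled knockout over wild type with a standard error (SE). The SE was worked back from the test, as the absolute log2 fold change divided by the square root of its F statistic. Levels are CPM, reads of a gene relative to the library total after TMM scaling, as mean ± SD over 5 libraries. Where a gene had 0 counts in a group, its fold is a lower bound against a floor of 3 counts over the group. Where it had 1 to 3 counts, the ratio is given with an exact 95% interval. Such intervals and floors cover counting error only. The level of Il6 was compared with an exact two-sided permutation test of log2(CPM + 1) over the 252 splits of 5 against 5 libraries, which cannot give a p below 0.00794. Distances between libraries were taken over log2 CPM (prior count 2) of the 500 most variable genes and tested in the same way.

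A set of 36 gene lists was tested with camera on log2 CPM with a preset correlation between genes of 0.01, and Benjamini-Hochberg adjustment over the lists. Their topics were the IL-6 family and its JAK-STAT3 pathway, STAT3 targets and acute-phase genes, and markers of rods, cones, bipolar, amacrine, horizontal and ganglion cells, Muller glia, astrocytes, microglia, and endothelial cells with pericytes. Other lists covered reactive gliosis, complement, interferon-stimulated genes, tubulins, microtubule-associated proteins, transport motors, neurofilaments with actin, and synaptic vesicles. Further lists covered mitochondrial transcripts, oxidative phosphorylation, redox genes, neurotrophic factors, extracellular matrix, heat shock, immediate early genes, the circadian clock and ribosomal proteins. Tissue lists covered retinal pigment epithelium, lens, cornea with ciliary body, muscle and erythroid cells. Sex-linked markers and genes that diverge between C57BL/6 substrains made up the rest. Of the listed genes, 11 were not analysed here and others were left out of the tests by the low-count filter, so list counts in the text are of tested members. Fisher's exact test compared the share of genes called within 10 Mb of Il6 with the rest of the genome.

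Genes named in the text follow a fixed rule. It takes Il6, Il6ra, Il6st, Stat3, Socs3 and Gfap whatever their result. It then takes the 12 higher and 12 lower called genes with the largest absolute log2 fold change among those averaging at least 1 CPM, passing over predicted-gene and clone names (5 higher and 14 lower). It adds up to 4 members of each list with the smallest p, called genes near Il6, and the most abundant members of the other-tissue lists. Any other gene was chosen after its values were seen. The groups, lists, tests, naming rule and most alternatives were fixed before the data were examined. Those alternatives were DESeq2, limma-voom, DESeq2 size factors and upper-quartile factors in edgeR, no filter or 1 CPM in 5 libraries, an adjusted p under 0.1, a fold threshold, 1 surrogate variable from svaseq, each library left out in turn, and leaving out other-tissue genes, genes near Il6 or sex chromosome genes. For the lists they were an estimated correlation, fry and 1 surrogate variable. Leaving out pseudogenes, leaving out genes that part the wild-type libraries, leaving out W5 and K5 together, and the exact permutation of list means were chosen after seeing the data.

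The pipeline was tested on simulated data with 50 genes changed at each of 4 fold sizes among 18675 genes tested for this comparison. It recovered 14% of the genes changed 1.25-fold, 46% at 1.5-fold, 72% at 2-fold and 100% at 4-fold, with 7 false calls among 123. When the microglia list alone was raised 1.5-fold, camera called 1 of the 36 lists, the one raised. Simulated genes varied independently of one another, so this does not test how camera's preset correlation handles genes that vary together. Processed pseudogenes were matched to parent transcripts with BLAST 2.17.0. Other software was R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, sva 3.50.0, Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.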

Results

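The data are gene-level RNA sequencing counts from the retinas of untreated mice aged 3 months, with 5 libraries of wild type and 5 labelled as knockout for interleukin-6 (IL-6), a cytokine that signals through the receptor subunit gp130 and the transcription factor STAT3. Wild-type libraries are called W1 to W5 and libraries labelled knockout K1 to K5. Total counts were 30433373, 33156742, 38518301, 38857374 and 34967652 in W1 to W5, and 38517067, 34603815, 35523452, 34051929 and 32783048 in K1 to K5. The only contrast the labels give is genotype, read here as asking how the uninjured retina differs when Il6 is disrupted. The labels give no litter, so differences may also come from the genetic background of the groups. This contrast cannot tell the effects apart.

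Il6 itself was read first, because it checks the labels, and its counts went against them. Il6 (ENSMUSG00000025746.11, chromosome 5, 30013114 to 30019981, GRCm38) had 0, 0, 1, 1 and 1 counts in W1 to W5 and 3, 3, 5, 7 and 4 counts in K1 to K5. The means were 0.6 ± 0.548 counts in wild type and 4.4 ± 1.67 counts in the libraries labelled knockout (SD, n = 5), or 0.0162 ± 0.0149 and 0.127 ± 0.0524 CPM. The ratio of the summed counts, 22 against 3, was 7.33 on the CPM scale, with a 95% counting interval of 2.2 to 38.3. The exact permutation test of log2(CPM + 1) gave a difference of 0.15 with p = 0.00794, the smallest that splits of 5 against 5 allow. The Il6tm1Kopf allele interrupts the gene with an inserted cassette, and gene-level counts do not separate the parts of the gene, so reads outside the interrupted part check nothing. Directions below are therefore those of the libraries as labelled. Il6 was too low for the edgeR fit.

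**Figure D1:**
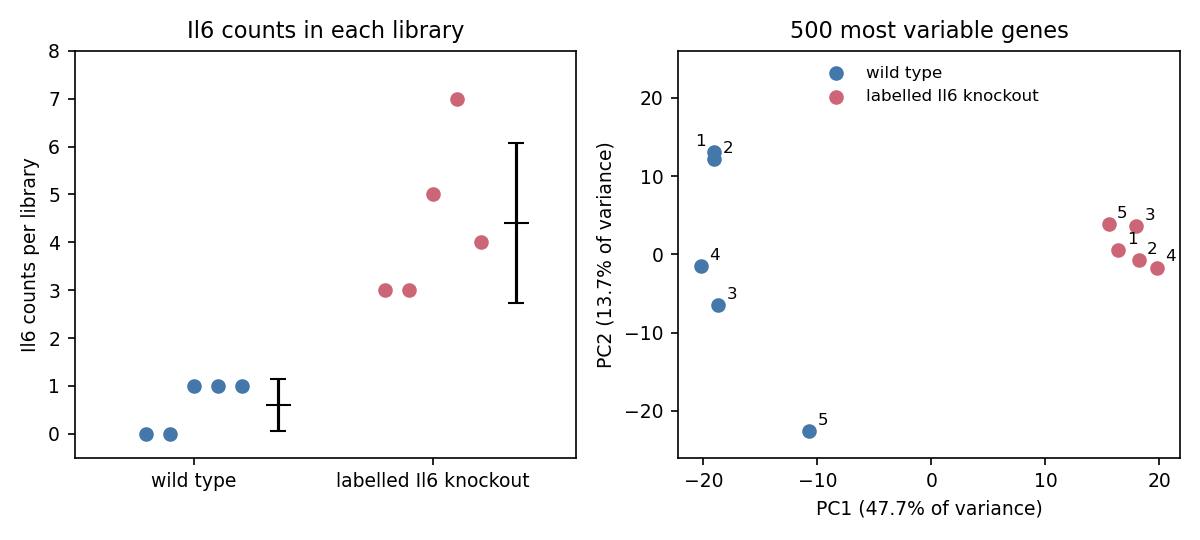
Left, Il6 counts in each of the 10 libraries, with the mean ± SD of each group of 5: wild-type libraries hold 0 or 1 count and libraries labelled knockout 3 to 7. Right, the first 2 principal components (47.7% and 13.7% of variance) of the 500 most variable genes, where numbers name the libraries: the groups lie apart on the first, and W5 lies at -10.73 while the other wild-type libraries lie between -20.2 and -18.72.

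The receptor and signalling genes downstream of IL-6 did not pass the test. Il6ra, the ligand-binding receptor subunit, stood at 0.799 ± 0.150 CPM in wild type and 0.954 ± 0.244 CPM in libraries labelled knockout, and Il6st, which encodes gp130, at 144 ± 10.2 and 138 ± 11.6 CPM. Stat3 stood at 63.3 ± 2.38 and 65.8 ± 2.85 CPM. Socs3, the feedback inhibitor induced by STAT3, stood at 3.78 ± 0.643 and 4.30 ± 0.706 CPM, and Gfap, an intermediate filament of astrocytes and reactive Muller glia, at 7.80 ± 2.44 and 9.97 ± 1.87 CPM. Their log2 fold changes were 0.25, -0.06, 0.05, 0.19 and 0.36, with edgeR adjusted p of 0.719, 0.804, 0.748, 0.677 and 0.436.

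Across the transcriptome, 385 of 18965 tested genes (2.03%) differed between the groups, 163 higher and 222 lower in the libraries labelled knockout. With a log2 fold change of at least 0.5 in size as a further condition, 127 genes were higher and 174 lower. Of the called genes, 276 code for protein (134 higher, 142 lower) and 45 are processed pseudogenes (4 higher, 41 lower), which are reverse-transcribed copies of other genes. Genes that rose include the interferon-induced Oasl2, the metallothionein Mt1 and the smooth muscle gene Lmod1, and genes that fell include the serpin Serpina3n and the rod arrestin Sag. In 660 tested genes (3.48%), 309 of them called, every library of one group lay above every library of the other, where chance gives 0.794%. The median log2 fold change of all tested genes was 0.0018. An unadjusted edgeR p under 0.05 was reached by 2620 of the 18965 genes, the rate to set beside counts at that threshold below. In the authors' deposited comparison, an adjusted p under 0.05 was given to 721 genes (320 higher, 401 lower), and 47 were marked significant (5 higher, 42 lower). That mark needs an absolute deposited log2 fold change above 1. The deposited values can be smaller in size than those here, as in Eno1b (-1.77 against -7.05), Tnfrsf8 (0.356 against 2.28) and Wdfy1 (-1.24 against -1.47). The 47 are therefore not a count of genes above that size on the scale used here. Of the 385 genes, 379 were among those 721, all 379 in the same direction. The count higher was 253 without W2, 93 without K3, 71 without K4 and 84 without K5, and the count lower was 140 without K4. DESeq2 called 319 higher and 444 lower, and 1 surrogate variable gave 303 and 355. Without a low-count filter the counts were 298 and 406. Leaving out W5 and K5 together, chosen after the data were seen, gave 107 higher, and among the genes named below it ended the calls of Rec8, Gbp4, Lif, Vip, Igf2, C1qc, Ifit1, Irf7, Rsad2, Map2, Syt2, mt-Rnr1, Gstm1, Gclc and Vcan.

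**Figure D2:**
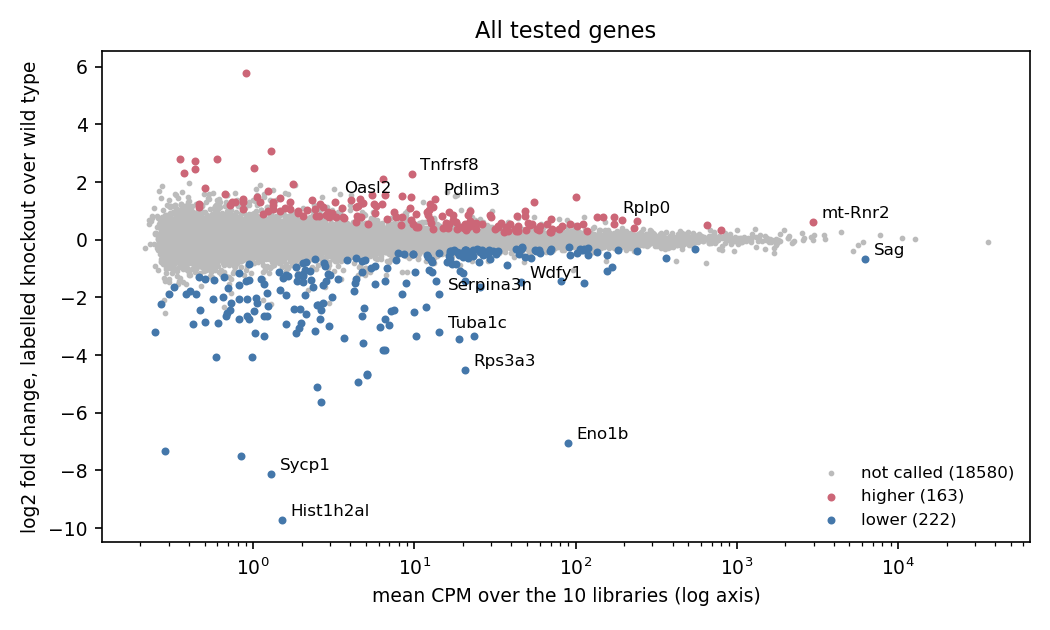
Each point is 1 of the 18965 tested genes, with its mean CPM on a log axis and its log2 fold change of libraries labelled knockout over wild type. The 163 genes called higher are red, the 222 called lower are blue, and the genes of large negative change include Hist1h2al, Sycp1, Eno1b and Rps3a3.

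The 12 named genes that rose most have varied known functions. Tnfrsf8, which encodes the lymphocyte receptor CD30 (ENSMUSG00000028602.12, chromosome 4, 145267137 to 145315164), went from 3.31 ± 2.26 to 16.1 ± 1.83 CPM, a log2 fold change of 2.28 ± 0.43 (SE, n = 5) with an edgeR adjusted p of 0.0108. It stood at 0.124 CPM in W2, and the authors' deposited DESeq2 adjusted p for it was 0.0661. Oasl2, an interferon-induced gene (ENSMUSG00000029561.17, chromosome 5, 114896936 to 114912234), went from 5.01 ± 1.49 to 14.1 ± 1.21 CPM, and its log2 fold change was 1.48 ± 0.17 with an edgeR adjusted p of 0.000162. Lmod1, a leiomodin of smooth muscle, went from 2.79 ± 1.03 to 8.16 ± 1.68 CPM (log2 fold change 1.55, edgeR adjusted p = 0.000905). Pdlim3, a protein of muscle Z-discs, went from 7.29 ± 2.84 to 19.6 ± 3.44 CPM (1.43, 0.00189). Mcm6, a subunit of the replicative helicase, rose by 1.37 (0.0132). W5 lay apart from the other wild-type libraries in Lmod1, at 4.56 CPM against 1.95 to 2.69, and in Mcm6, at 4.50 CPM against 1.22 to 2.10.

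The other genes of this set were less certain. For St6galnac2, Dnm3os and Dnah7c the doubt lies in the assignment of reads. All 23 alternatives called Dnm3os, Dnah7c and ENSMUSG00000110170.1 of St6galnac2. For the rest the doubt lies in the calls. St6galnac2, a sialyltransferase, appears under 2 overlapping identifiers, which rose by 1.56 (ENSMUSG00000110170.1) and 0.83 (ENSMUSG00000057286.6) with edgeR adjusted p of 0.000237 and 1.65e-05. Dnm3os, an antisense transcript, rose by 1.41 (0.00508), and its reads could come from the opposite strand because the strand setting is not given. Dnah7c, an axonemal dynein with close copies, rose by 1.36 (0.0118). Rec8, a meiotic cohesin, rose by 2.09 (0.0340), Capn11, a testis calpain, by 1.93 (0.0298), Gbp4, an interferon-induced GTPase, by 1.48 (0.0347), and the pseudogene Smarca5-ps by 1.70 (0.0234). Rec8 lost its call without W5, K2, K3, K4 or K5, Capn11 without W1, W3, K1, K2 or K4, Gbp4 without W1, W4, K3, K4 or K5, and Smarca5-ps without K3, K4 or K5, and limma-voom did not call Capn11 or Gbp4. Over all alternatives the adjusted p ran from 0.000114 to 0.14 for Rec8, 0.000463 to 0.105 for Capn11, 0.00153 to 0.12 for Gbp4 and 0.000199 to 0.0716 for Smarca5-ps.

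Several of the named genes that fell most are near-identical copies of other genes. Eno1b, a copy of the glycolytic enzyme gene Eno1 (ENSMUSG00000059040.4, chromosome 18, 48045335 to 48048378), went from 179 ± 86.8 to 1.34 ± 0.611 CPM, a log2 fold change of -7.05 ± 0.34 (SE, n = 5) with an edgeR adjusted p of 9.97e-09. Rps3a3, a copy of a ribosomal protein gene (chromosome 13, 108670603 to 108671397), went from 39.3 ± 14.6 to 1.70 ± 0.498 CPM, with a log2 fold change of -4.52 ± 0.25 and an edgeR adjusted p of 3.36e-08. Nudc-ps1, Eif3j2, Rpl15-ps2 and the tubulin gene Tuba1c had log2 fold changes of -3.06, -3.41, -2.93 and -3.22, with edgeR adjusted p of 7.95e-07, 0.00218, 0.0396 and 0.00109. Reads of these copies and of their parents can be assigned to one another, so their levels are uncertain. Hist1h2al, a histone copy, had 531 counts in wild type and 0 in the libraries labelled knockout, at least 177-fold lower against a floor of 3 counts over the group (edgeR adjusted p = 2.63e-05).

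Sycp1, which builds the synaptonemal complex of meiotic cells (ENSMUSG00000027855.13, chromosome 3, 102818499 to 102936100), had 459 counts in wild type and 1 count, in K3, in the libraries labelled knockout. The ratio of wild type over labelled knockout was 459, with a counting interval of 82 to 18200 (edgeR adjusted p = 2.41e-07). Tgm3, an epidermal transglutaminase, went from 9.85 ± 7.26 to 0.388 ± 0.169 CPM (log2 fold change -4.66, edgeR adjusted p = 0.00160). Orm2, an acute-phase orosomucoid, went from 2.13 ± 1.20 to 0.207 ± 0.108 CPM (-3.35, 0.00571), and Rtkn2, which encodes a GTPase effector, from 18.6 ± 15.9 to 1.84 ± 0.266 CPM (-3.33, 0.0132). Some wild-type libraries lay near the labelled knockout mean, W5 in Tgm3 (0.38 CPM) and W3 in Orm2 (0.13 CPM). So did W4 and W5 in Rtkn2 (2.47 and 1.87 CPM), and W5 in Eif3j2 (0.53 CPM against 0.63). In Rpl15-ps2, W2 and W5 stood at 0.37 and 0.24 CPM against 0.37. The levels of these genes therefore did not follow the label in every library. limma-voom did not call Tgm3, Orm2, Rtkn2, Eif3j2, Tuba1c or Rpl15-ps2, with adjusted p of 0.195, 0.185, 0.295, 0.144, 0.0723 and 0.347, while their lowest adjusted p over all alternatives were 3.23e-08, 6.55e-06, 5.19e-06, 1.86e-07, 1.23e-08 and 0.00029. Rpl15-ps2 also lost its edgeR call when any library other than W2 or W5 was left out (highest adjusted p 0.108).

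**Figure D3:**
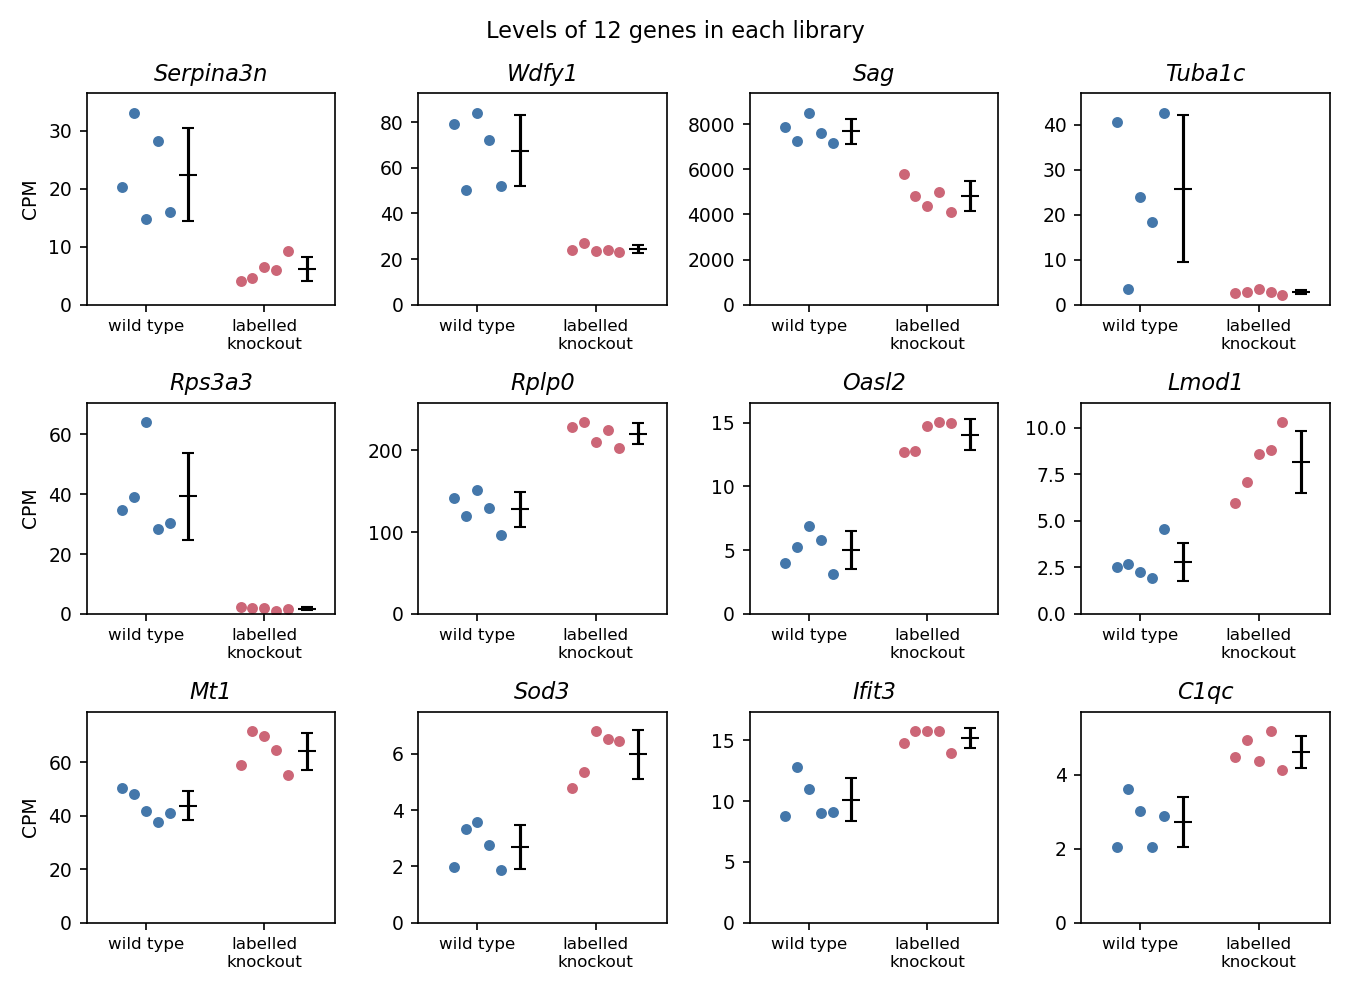
CPM of 12 genes in each of the 5 wild-type libraries (blue) and the 5 libraries labelled knockout (red), with the mean ± SD of each group beside the points. Serpina3n, Wdfy1, Sag, Tuba1c and Rps3a3 were lower and the other genes higher in the libraries labelled knockout, and Tuba1c in W2, at 3.46 CPM, lies near the labelled knockout level.

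Of the 36 gene lists, camera called 10, all of them higher in the libraries labelled knockout. With a correlation estimated for each list the count was 0, as it was with fry's directional test and with an exact permutation of the list means. Fry's mixed test, which takes changes in either direction, was not used for these counts. Its adjusted p ran from 2.38e-05 for STAT3 targets to 0.9635 for lens markers. It was under 0.05 for some lists that camera did not call, such as amacrine markers (3.47e-05). The count was 6 without W1, 6 without W3, 3 without W4, 5 without W5, 5 without K1 and 6 without K3.

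**Figure D4:**
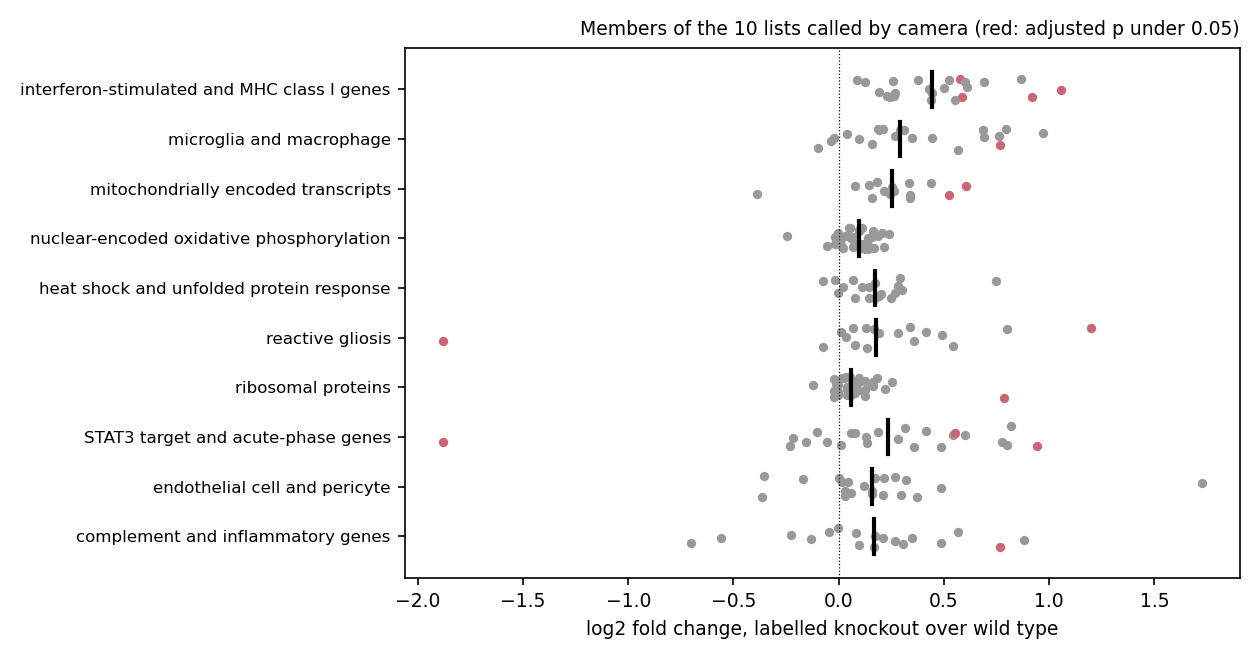
Log2 fold change (libraries labelled knockout over wild type) of every tested member of the 10 lists called by camera, with genes of edgeR adjusted p under 0.05 in red and the median of each list as a black bar. All 23 interferon-stimulated and MHC class I members lie above 0, and Serpina3n lies at -1.88 in both lists that hold it.

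Interferon-stimulated and MHC class I genes formed the most uniform list. All 23 tested members had a positive log2 fold change (median 0.44), and 4 rose, with 14 higher when adjusted over the list alone (9 called by DESeq2, 3 by limma-voom). Ifit3 and Ifit1, which restrict viral RNA, rose from 10.1 ± 1.74 to 15.2 ± 0.820 CPM and from 2.15 ± 0.509 to 4.06 ± 0.683 CPM, with log2 fold changes of 0.59 ± 0.11 and 0.92 ± 0.19 (SE, n = 5) and edgeR adjusted p of 0.0118 and 0.0184. The interferon regulator Irf7 rose by 0.58 (edgeR adjusted p = 0.0340) and the antiviral gene Rsad2 by 1.06 (0.0461). Camera gave the list an adjusted p of 1.13e-12, against an adjusted p of 0.635 with an estimated correlation. The mean of the list lay above every wild-type library in 4 of the 5 libraries labelled knockout (exact permutation p = 0.0159, adjusted 0.286). Ifit1 lost its call without K3, K4 or K5, Irf7 without W1, W3, W4, K3, K4 or K5 and with limma-voom, and Rsad2 without any library except W2 or K1, with limma-voom, with upper-quartile factors, with at least 1 CPM in 5 libraries and without pseudogenes. Over all alternatives the adjusted p ran from 0.000134 to 0.101 for Ifit1, 0.00186 to 0.111 for Irf7 and 0.00351 to 0.218 for Rsad2. Outside the list, Gbp2b, of the same GTPase family as Gbp4 and named after its values were seen, was called lower. It had 298 counts in wild type and 1 in the libraries labelled knockout, a ratio of 298 with a counting interval of 53.1 to 11800.

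Microglia and macrophage markers leaned the same way. Of 21 tested markers, 18 had a positive log2 fold change (median 0.29), 1 rose and 6 were higher when adjusted over the list alone, with summed levels of 74.9 ± 13.9 CPM in wild type and 86.7 ± 1.91 CPM in libraries labelled knockout. The gene that rose was C1qc, a subunit of complement C1q, from 2.72 ± 0.676 to 4.62 ± 0.431 CPM (log2 fold change 0.77 ± 0.18, edgeR adjusted p = 0.0342). Camera gave the list an adjusted p of 1.96e-05, against an adjusted p of 0.635 with an estimated correlation (exact permutation p = 0.0159, adjusted 0.286). In the complement and inflammatory list, C1qc was the only gene of 18 called by edgeR, 3 were higher when adjusted over the list alone, and the camera adjusted p was 0.0491, or an adjusted p of 0.962 with an estimated correlation. DESeq2 called 3 genes in each of these lists, C1qc and C1qb in both with Tyrobp or C4b, and limma-voom called C1qc in both and C4b. C4b was called without W2, without a low-count filter and with 1 surrogate variable as well (edgeR adjusted p = 0.0957, and 0.00149 to 0.359 over all alternatives), C1qb without W2 (0.0159 to 0.409), Tyrobp with 1 surrogate variable (0.0262 to 0.181), and Trem2 without W2 and with 1 surrogate variable (0.0375 to 0.311). Il18, with a negative log2 fold change, was called without W3 (0.0336 to 0.477). C1qc lost its call without any library except W2 or K1 (adjusted p from 0.000933 to 0.105 over all alternatives), and the complement list without any library except W2 or K4 (0.0542 to 0.204).

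Called STAT3 targets and gliosis genes moved in both directions, while 18 of 24 and 16 of 18 tested members had a positive log2 fold change. Mt1 and Mt2, metallothioneins that bind zinc, rose from 43.8 ± 5.40 to 64.1 ± 7.05 CPM and from 3.92 ± 0.698 to 7.53 ± 1.64 CPM, with log2 fold changes of 0.55 ± 0.09 and 0.94 ± 0.17 (SE, n = 5) and edgeR adjusted p of 0.00473 and 0.00676. Serpina3n, an acute-phase serine protease inhibitor (ENSMUSG00000021091.8, chromosome 12, 104406729 to 104414329), fell from 22.4 ± 7.95 to 6.11 ± 2.05 CPM (-1.88 ± 0.24, edgeR adjusted p = 0.00044). Of 24 tested STAT3 target and acute-phase genes, 2 rose, 1 fell and 21 did not pass, with 4 higher and 1 lower when adjusted over the list alone (median 0.23; DESeq2 called 4 and limma-voom 3). The camera adjusted p was 0.0278, and the adjusted p was 0.962 with an estimated correlation. In the reactive gliosis list of 18, Lif rose and Serpina3n fell, with 4 higher and 1 lower when adjusted over the list alone (DESeq2 called 4 and limma-voom 1), and the camera adjusted p of 0.0165 became an adjusted p of 0.962 with an estimated correlation. W2 stood apart in the summed level of that list, at 621 CPM against 447 to 488 in the other wild-type libraries. The STAT3 target list lost its call without W3, W4, W5, K3 or K5 (adjusted p 0.0528 to 0.171) and the gliosis list without W4, W5 or K3 (0.0617 to 0.171). Lcn2, in both lists, was called with DESeq2, without W4, without a low-count filter, with 1 surrogate variable and without the genes that part the wild-type libraries (0.00415 to 0.167 over all alternatives), and Cd44 of the gliosis list with DESeq2, without K1 and without a low-count filter (0.0338 to 0.315), both with positive log2 fold changes.

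In the list of IL-6 family ligands, receptors and JAK-STAT3 genes, 1 of 24 tested genes rose. It was Lif, an IL-6 family cytokine that signals through gp130, from 0.433 ± 0.0969 to 0.995 ± 0.324 CPM (log2 fold change 1.20 ± 0.28, edgeR adjusted p = 0.0372). Adjusted over the list alone, 2 genes were higher, Lif among them, and DESeq2 called 2 and limma-voom 0. The list had a median of -0.03, a mean of 0.08 and an upward camera direction (adjusted p = 0.973), so its median differs in sign from its mean and test. Lif lost its call without W2, W3, W4, W5, K2, K4 or K5 and with limma-voom, and its adjusted p ran from 0.0107 to 0.158 over all alternatives.

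Camera called mitochondrial, oxidative phosphorylation, ribosomal protein and heat shock lists higher, with small medians. The ribosomal RNAs of the mitochondrial genome, mt-Rnr2 and mt-Rnr1, rose from 2353 ± 252.3 to 3584 ± 415 CPM and from 536 ± 84.3 to 771 ± 126 CPM, with log2 fold changes of 0.61 ± 0.11 and 0.52 ± 0.12 (SE, n = 5) and edgeR adjusted p of 0.00537 and 0.0375. Among the 15 mitochondrially encoded transcripts 2 rose, 6 were higher when adjusted over the list alone, and 14 had a positive log2 fold change (median 0.25). Mitochondrial genes took 2.98% to 3.84% of counts in wild type and 3.38% to 4.44% in libraries labelled knockout. The camera adjusted p was 2.01e-05, and the adjusted p was 0.962 with an estimated correlation. Of 35 nuclear genes of oxidative phosphorylation 30 had a positive value (median 0.09), but edgeR called 0 (5 at an unadjusted p under 0.05, 0 by DESeq2 and 0 by limma-voom). Their camera adjusted p was 0.00419, and the adjusted p was 0.962 with an estimated correlation. mt-Rnr1 lost its call without W1, W4, W5, K2, K4 or K5 (adjusted p from 0.00217 to 0.111 over all alternatives), and the oxidative phosphorylation list without W1, W4 or K1 (0.0739 to 0.171). Ndufb9 of that list and mt-Co3 were called higher without W2 and with 1 surrogate variable (0.0318 to 0.405 and 0.0306 to 0.314 over all alternatives), and mt-Nd3 without a low-count filter (0.0499 to 0.398).

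Of 37 ribosomal protein genes, 1 rose and 28 had a positive value (median 0.06). Rplp0, a component of the ribosomal stalk, rose from 128 ± 21.1 to 220 ± 13.3 CPM (log2 fold change 0.79 ± 0.10, edgeR adjusted p = 0.000416), and it was the only gene higher when adjusted over the list alone. Rplp0 has near-identical pseudogenes, so its level is uncertain. The list's camera adjusted p was 0.0262, and the adjusted p was 0.962 with an estimated correlation. Of 20 heat shock and unfolded protein response genes, edgeR called 0 (3 at an unadjusted p under 0.05, 0 by DESeq2 and 0 by limma-voom), 17 had a positive value (median 0.17), and the camera adjusted p was 0.00854, or an adjusted p of 0.962 with an estimated correlation. The ribosomal list lost its call without W1, W3, W4, W5, K1 or K2 (0.0524 to 0.46), and the heat shock list without W4 or K1 (0.204 and 0.172).

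edgeR called a single photoreceptor marker. Sag, the rod arrestin that ends the light response (ENSMUSG00000056055.13, chromosome 1, 87803680 to 87845158), fell from 7682 ± 540 to 4819 ± 646 CPM (log2 fold change -0.67 ± 0.11, SE, n = 5, edgeR adjusted p = 0.00267). It was the only gene called by edgeR or limma-voom of 24 rod markers, and 1 marker was higher and 1 lower when adjusted over the list alone. DESeq2 also called Guca1b, a guanylate cyclase activator of photoreceptors, in the other direction (log2 fold change 0.37), as did 1 surrogate variable and the fit without W2 (edgeR adjusted p = 0.0722, and 0.00902 to 0.198 over all alternatives). Nr2e3 was called higher with 1 surrogate variable (0.0385 to 0.318) and Abca4 lower without K1 (0.033 to 0.505). Summed rod markers stood at 104400 ± 10810 and 97090 ± 13600 CPM, and the camera adjusted p was 0.767. Of 17 cone markers edgeR called 0 (1 at an unadjusted p under 0.05, 0 by DESeq2 and 0 by limma-voom; camera adjusted p = 0.767). In the cone phosphodiesterase gene Pde6c, W5 stood at 106 CPM against 35.4 to 45.7 in the other wild-type libraries, and the group means were 54.2 ± 29.4 and 89.7 ± 10.5 CPM. Pde6c was not called (edgeR adjusted p = 0.15), but it was without W5 (8.38e-06), without W5 and K5 together (5.81e-05) and without a low-count filter (0.0124), and its adjusted p ran from 8.38e-06 to 0.289 over all alternatives.

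edgeR called single genes among markers of inner retinal neurons and glia. Vip, a neuropeptide of amacrine cells, fell from 23.3 ± 2.18 to 18.2 ± 1.41 CPM (log2 fold change -0.35 ± 0.09, edgeR adjusted p = 0.0480), 1 of 20 amacrine markers, with 1 higher and 1 lower when adjusted over the list alone, while DESeq2 also called Npy, with a positive log2 fold change. Igf2, a growth factor placed among 9 astrocyte markers, fell from 78.6 ± 12.1 to 59.5 ± 3.47 CPM (-0.40 ± 0.09, edgeR adjusted p = 0.0388), also when adjusted over the list alone. edgeR called 0 of 19 bipolar, 10 horizontal, 23 ganglion cell and 20 Muller glia markers, against 2, 3, 2 and 2 at an unadjusted p under 0.05. limma-voom called 0 in each, and DESeq2 called only the bipolar genes Cabp5 and Neto1, the 2 that were lower when adjusted over the list alone. Camera adjusted p was 0.854 for amacrine, 0.767 for astrocyte, 0.928 for bipolar, 0.190 for horizontal, 0.297 for ganglion cell and 0.767 for Muller glia markers. The bipolar list had a median of 0.03, a mean of -0.02 and a downward direction, and the astrocyte list a median of 0.0015, a mean of -0.04 and a downward direction. W2 stood apart in summed Muller glia markers, at 11400 CPM against 8289 to 9156. Vip lost its call without any 1 library, with limma-voom, with upper-quartile factors and without pseudogenes (adjusted p from 0.00985 to 0.182 over all alternatives), and Igf2 without W2, W3, W4 or any of K1 to K5 and with limma-voom (0.00659 to 0.11). Without W2 the Muller glia list was called (camera adjusted p = 0.0125), without K5 the horizontal cell list (0.0373), and without W3 the gene Neto1, which was also called without a low-count filter (0.0144 to 0.271 over all alternatives). Cabp5 (edgeR adjusted p = 0.0506) was called in 10 of 23 alternatives (0.00674 to 0.153), among them upper-quartile factors, no low-count filter, 1 surrogate variable and the fits without W2, W4 or K2. The Muller glia genes Dbi and Apoe were called higher without W2 (0.00401 to 0.297 and 0.00979 to 0.711 over all alternatives), and Dbi with 1 surrogate variable too.

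Cytoskeletal and synaptic lists were not called, and a single gene fell in 3 of them. Tuba1c fell among 27 tubulins and tubulin modifiers, from 25.8 ± 16.3 to 2.77 ± 0.486 CPM (log2 fold change -3.22, edgeR adjusted p = 0.00109; 0.0723 with limma-voom, and as low as 1.23e-08 over all alternatives). Map2, a dendritic microtubule-associated protein, fell from 617 ± 27.8 to 490 ± 43.4 CPM (-0.33 ± 0.08, edgeR adjusted p = 0.0358), 1 of 30 in its list. Syt2, a calcium sensor of synaptic vesicles, fell from 47.6 ± 2.03 to 38.3 ± 3.84 CPM (-0.32 ± 0.07, edgeR adjusted p = 0.0388), 1 of 24. Each was also the 1 gene lower when adjusted over the list alone. edgeR called 0 of 32 transport motors and 0 of 22 neurofilament and actin genes (3 and 0 at an unadjusted p under 0.05), and DESeq2 and limma-voom called 0 in both. Camera adjusted p was 0.910, 0.726, 0.531, 0.767 and 0.767 for tubulins, microtubule-associated proteins, synaptic vesicle genes, motors and neurofilaments with actin. The tubulin list had a median of 0.02, a mean of -0.09 and an upward direction, and the motor list a median of 6e-04, a mean of -0.01 and a downward direction. Map2 lost its call without any library except W2 or K1 (adjusted p from 0.002 to 0.116 over all alternatives), and Syt2 without W1, W3, W5, K1, K2, K4 or K5 (0.00929 to 0.137). Tuba1a was called higher without W2 (0.0416 to 0.709).

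Redox genes moved in both directions. Sod3, the extracellular superoxide dismutase, rose from 2.70 ± 0.773 to 5.99 ± 0.867 CPM (edgeR adjusted p = 0.00426), and Gstm1, a glutathione transferase with close paralogs, from 16.9 ± 1.76 to 24.4 ± 2.84 CPM (log2 fold change 0.54 ± 0.10, SE, n = 5, 0.00772). Gclc, which makes the first step of glutathione synthesis, fell from 50.8 ± 2.65 to 42.2 ± 2.34 CPM (-0.27 ± 0.06, 0.0415). Of the 30 redox genes, 2 were higher and 2 lower when adjusted over the list alone (camera adjusted p = 0.726). Vcan, a matrix proteoglycan, rose from 1.58 ± 0.353 to 3.29 ± 0.830 CPM (1.06 ± 0.21, edgeR adjusted p = 0.0160), 1 of 29 extracellular matrix genes and the 1 gene higher when adjusted over the list alone, in a list with a median of -0.02, a mean of 0.06 and an upward direction (camera adjusted p = 0.817). Among 21 neurotrophic factors and receptors edgeR called Lif alone, DESeq2 Lif and Kdr and limma-voom 0, 1 gene was higher and 1 lower when adjusted over the list alone, and the camera adjusted p was 0.767. Gclc lost its call without any library except W2 or K1 and without a low-count filter (adjusted p from 0.00989 to 0.127 over all alternatives), and Vcan without K3 (0.000124 to 0.0836). Gstm1 lost it without W5 and K5 together (5.22e-05 to 0.0548), and Lif as described with the IL-6 family (0.0107 to 0.158). Slc7a11 was called lower without W2, without a low-count filter and with 1 surrogate variable (0.000645 to 0.316), and Sparc of the matrix list higher without W2 and with 1 surrogate variable (0.0162 to 0.299).

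Immediate early and clock genes were not called by edgeR as set out in the methods. It called 0 of 18 and 0 of 22 (4 and 5 at an unadjusted p under 0.05), limma-voom 0 in both, and DESeq2 only the clock gene Bhlhe40, which was the 1 gene lower when adjusted over the list alone. Camera adjusted p was 0.297 and 0.190. The clock list was called without K2 (0.0188), and Bhlhe40 without W4 or K2, without a low-count filter and with 1 surrogate variable (0.0107 to 0.224 over all alternatives). Per1, with a negative log2 fold change, was called without a low-count filter (0.0407 to 0.332).

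Markers of vessels and of neighbouring tissues were read as a check on dissection. Of 21 endothelial and pericyte markers 18 had a positive value (median 0.16), and edgeR called 0 (6 at an unadjusted p under 0.05, 0 by limma-voom). DESeq2 called 1, the endothelial receptor gene Kdr, whose log2 fold change was negative (-0.36), against the direction of the list. Their summed level was 672 ± 74.6 CPM in wild type and 655 ± 44.3 CPM in libraries labelled knockout, so the sum and the median differ in direction. Their camera adjusted p was 0.0418, and the adjusted p was 0.962 with an estimated correlation. Summed markers in wild type and in libraries labelled knockout were 901 ± 278 and 871 ± 104 CPM for retinal pigment epithelium, 3.30 ± 0.373 and 3.54 ± 0.445 CPM for lens, and 190 ± 17.2 and 220 ± 19 CPM for cornea with conjunctiva and ciliary body. They were 28.3 ± 10.4 and 24.9 ± 2.60 CPM for skeletal muscle and 115 ± 24.9 and 123 ± 9.50 CPM for erythroid cells. edgeR called 0 of the 18, 5, 15, 7 and 7 tested markers (0, 0, 3, 2 and 0 at an unadjusted p under 0.05), limma-voom 0 in each, and DESeq2 only Mab21l1 of the cornea list, also the 1 gene higher when adjusted over the list alone, and Tnnt3 of the muscle list. Camera adjusted p was 0.583, 0.760, 0.767, 0.767 and 0.767. The cornea list had a median of -0.07, a mean of -0.16 and an upward direction. K2 stood apart in the lens sum, at 4.32 CPM against 3.27 to 3.52, and in the cornea sum, at 187 CPM against 222 to 236. The endothelial list lost its call without W1, W3, W4, W5, K1, K2 or K3 (0.0845 to 0.204), and the pigment epithelium list was called without W2 (0.0233). Kdr was called without W1 (0.0195 to 0.281 over all alternatives) and Mab21l1 without W3 or K2 (0.0267 to 0.207), and both without a low-count filter and with 1 surrogate variable. Slco1a4 was called higher without W2 (0.00133 to 0.42), Anpep without a low-count filter (0.0224 to 0.385) and Wfdc1 of the cornea list without W2 (0.0413 to 0.585).

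Sex and substrain markers were compared as a check of the animals behind the labels. The Y-linked gene Ddx3y stood at 82.6 ± 3.41 and 81.2 ± 4.60 CPM, and edgeR, DESeq2 and limma-voom called 0 of 4 sex-linked markers (0 at an unadjusted p under 0.05, camera adjusted p = 0.767). Those 4 were the Y-linked genes Uty, Ddx3y, Eif2s3y and Kdm5d, while Xist and Tsix did not pass the low-count filter. The narrow spread of Ddx3y leaves no library without Y-linked reads, so every library held male tissue. Of 8 tested genes known to differ between C57BL/6 substrains, 1 rose and 1 fell, as they did when adjusted over the list alone (camera adjusted p = 0.297). Wdfy1, an endosomal adaptor (ENSMUSG00000073643.11, chromosome 1, 79702262 to 79776143), fell from 67.6 ± 15.5 to 24.3 ± 1.67 CPM (log2 fold change -1.47 ± 0.13, edgeR adjusted p = 8.14e-06). Fgfbp3, a carrier of fibroblast growth factors, rose from 13.3 ± 3.93 to 21.6 ± 3.40 CPM (0.70 ± 0.17, edgeR adjusted p = 0.0420). Nnt, which C57BL/6J mice carry with a deletion, stood at 0.408 ± 0.150 and 0.312 ± 0.0942 CPM. Fgfbp3 lost its call without any library except W2 or W5 (adjusted p from 0.00198 to 0.126 over all alternatives).

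Genes near Il6 were examined because the allele was made in cells of another mouse strain, whose sequence can remain beside the targeted gene on a C57BL/6 background. Within 10 Mb of Il6, edgeR called 0 of 255 tested genes, against 2.06% elsewhere (two-sided Fisher's exact p = 0.0113), with 28 at an unadjusted p under 0.05. Over all 18965 tested genes, 2620 lay under that unadjusted p. Neighbouring genes are not independent, so the Fisher's exact p-values of these windows overstate the evidence. DESeq2 called 5 within 10 Mb of Il6, Emilin1, 1700096K18Rik, Gm42528, Galnt11 and Fam126a, and limma-voom 0. Within 5 Mb the count was 0 of 137 (Fisher's exact p = 0.12, 18 at an unadjusted p under 0.05). Within 20 Mb it was 2 of 337 (Fisher's exact p = 0.0744), Gnat3 and Gm43508, named after their values were seen, with log2 fold changes of 1.29 and 1.33. Within 10 Mb, 2 genes were called without W1, 2 without K1 and 1 without K2, and the Fisher's exact p was 0.183 with DESeq2, 0.599 without W1, 0.137 without K1, 0.196 without K2, 0.0539 without K3, 0.122 without K4 and 0.082 without K5 (0.001 to 0.599 over all alternatives).

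The libraries separated by label. The mean distance over the 500 most variable genes was 44.05 between groups and 28.82 within them, with 35.09 within wild type and 22.55 within the libraries labelled knockout. The exact permutation test of between minus within, 15.23, gave p = 0.00794, the smallest possible.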

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

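The test of how far genes share a parting of the wild-type libraries, and the test of a mislabelled or mixed library, were chosen only after the partings had been seen. Single libraries were compared with the other 4 of their group by Dixon's ratio of gap to range. It marked 29 of 422 groups of values (6.87%), where chance marks about 1 in 20. Of the 29, 21 were in wild type, 10 of them in W2, and 8 in libraries labelled knockout.

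W2 lay above the other wild-type libraries in summed Muller glia markers, at 11400 CPM against 8289 to 9156, and in summed reactive gliosis genes, at 620.8 CPM against 447.1 to 488.5. W2 also lay above the others in Rlbp1, a Muller glia retinaldehyde-binding protein (712.5 CPM against 475.2 to 539), in complement C4b (6.305 against 2.132 to 3.279), in the transporter Slco1a4 (27.04 against 16.22 to 18.49), and in the cone opsin Opn1mw (200 against 133.1 to 148.1). Its ribosomal protein genes Rpl11, Rpl27 and Rps28 stood at 195, 93.86 and 95.35 CPM, against highest values of 153.2, 73.87 and 76.86 in the others. Its Eno1b stood at 331.1 CPM against 113.3 to 153.4.

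W5 lay apart on the first principal component, at -10.73 against -20.2 to -18.72, and in Lmod1 (4.559 CPM against 1.948 to 2.689), Mcm6 (4.5 against 1.216 to 2.098) and Pde6c (106.4 against 35.36 to 45.68). W4 had low values in the summed IL-6 family list (1230 CPM against 1308 to 1326) and in Bicd1 (40.95 against 44.72 to 46.11). W3 had high values in Mab21l1 (165.9 CPM against 132.7 to 136.8), Dync1li1 (134.3 against 115.7 to 119.3) and Arntl (104.4 against 95.46 to 97.51). W1 was high in Lif (0.6048 CPM against 0.3746 to 0.4018) and low in Zic1 (5.029 against 5.832 to 6.058).

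Among the libraries labelled knockout, K2 was high in summed lens markers (4.318 CPM against 3.269 to 3.522) and Wdfy1 (27.27 against 23.19 to 23.85), and low in summed cornea markers (187.4 against 222.2 to 236.4). K1 was high in Lrit3 (65.27 CPM against 45.71 to 50.13), Tyrobp (2.124 against 1.67 to 1.778) and Anpep (6.426 against 0.6599 to 1.225). K4 was high in Npy (14.91 CPM against 10.65 to 11.82). K3 held the only Sycp1 count of its group (0.02784 CPM against 0).

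The wild-type libraries were parted by 93 of 15362 genes, with a gap of at least 1.5 log2 CPM units, while 13 genes parted the libraries labelled knockout in that way. Of the 93, 26 were called between the groups (4 higher, 22 lower), among them Tuba1c and Tnfrsf8 (low in W2), Tgm3 and Eif3j2 (low in W5), Orm2 (low in W3) and Rtkn2 (low in W4 and W5). A single mislabelled or mixed wild-type library is argued against as the whole pattern, because the library set apart most often, W5, accounted for 20.4% of the genes (exact 95% interval 12.8 to 30.1) and the genes made 14 different partings. Chromosome segments that differ between the wild-type animals may account for part of it, since 10 of 33 pairs of these genes 1 to 10 Mb apart shared their parting, against 3.4 on average when partings were permuted (one-sided permutation p = 0.0021), although the genes were chosen for the pattern they show. The labels give no breeding record, and other biological differences between the animals were not tested and stay open.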

How the results depend on the processing

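The alternatives without pseudogenes, without the genes that part the wild-type libraries, without W5 and K5 together, and the exact permutation of list means were chosen only after the results were seen, while the others were planned. Genes higher and lower numbered 319 and 444 with DESeq2, 298 and 406 without a low-count filter, 303 and 355 with 1 surrogate variable and 291 and 360 at an adjusted p under 0.1, against 163 and 222. DESeq2 called 382 of the 385 genes, limma-voom 315 and the surrogate variable fit 385, and all 385 had the same direction in each of the 3. Without W5 and K5 together 107 genes were higher and 181 lower. With 1 library left out in turn, genes higher ranged from 71 (without K4) to 253 (without W2) and genes lower from 140 (without K4) to 289 (without W2). The adjusted p under 0.1 admits more genes by construction, and the cause was not tested for the other changes.

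Counts stayed within 1.5 times with limma-voom (167 and 175), DESeq2 size factors (169 and 222), upper-quartile factors (159 and 207), at least 1 CPM in 5 libraries (142 and 169), a log2 fold change of at least 0.5 (127 and 174), and without other-tissue genes (170 and 227), genes near Il6 (164 and 222), X and Y genes (166 and 224), pseudogenes (143 and 154) or genes that part the wild-type libraries (172 and 208). The share of called genes that were lower ran from 51.2% (limma-voom) to 66.4% (without K4).

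Camera called 10 lists, and the count was 10 with 1 surrogate variable. It was 0 with a correlation estimated for each list, 0 with fry's directional test and 0 with the exact permutation. With 1 library left out it ranged from 3 (without W4) to 12 (without W2). The estimated correlation replaces a preset of 0.01, and which genes drive the loss was not tested. Called genes near Il6 numbered 2 in the 20 Mb window and 5 with DESeq2, and ranged from 0 to 2 with 1 library left out, for which the cause was not tested. The Il6 difference was 0.94 with a pseudocount of 0.1, 0.15 with total counts and 0.12 to 0.16 with 1 library left out, with an exact permutation p of 0.00794 each time. The distance difference was 11.54 over all tested genes, 13.08 over a larger set of variable genes and 14.12 to 19.79 with 1 library left out, again with an exact permutation p of 0.00794, the smallest possible in each case. 

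Single genes were followed under alternatives only where the naming rule takes them. Of 3771 values of 167 named genes, 3548 stayed on their side of the threshold, 148 lost the call and 75 gained it. The direction turned in 0 values of a gene called in either fit, but it turned under some alternatives for the uncalled genes Crybb3, Bfsp1, Bfsp2, Crygn, Hbb-bs, Ddx3y, Eif2s3y and Kdm5d. Of 47 called named genes, 23 kept their call and direction in every alternative, and 29 were called in each fit with 1 library left out. Low depth limits the wild-type level of Il6, which rests on 3 counts. It also limits the labelled knockout levels of Hist1h2al, Sycp1 and Gbp2b, which rest on 0, 1 and 1. No paired analysis was possible because the labels carry no replicate numbers.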

Other observations

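The chromosome counts, the other groupings of the libraries, the pseudogene tests and the Il6 tests in this part were chosen only after the results they bear on were seen. The called genes were unevenly spread over the chromosomes in 22 Fisher's exact tests. Chromosome 12 held 35 called genes of 733 tested (4.77%, adjusted p = 3.19e-05), 29 of them lower, and chromosome 4 held 41 of 1156 (3.55%, adjusted p = 0.0037). Chromosome 7 held 4 of 1490 (0.268%, adjusted p = 4.7e-08), chromosome 6 held 9 of 970 (0.928%, adjusted p = 0.0423) and the X chromosome 4 of 640 (0.625%, adjusted p = 0.034). On chromosome 18, 10 of 494 genes were called, all of them lower (adjusted p = 1). Neighbouring genes are not independent, so these p-values overstate the evidence.

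The 10 libraries were regrouped 5 against 5 in 100 of the possible ways. Only 1 grouping called at least 385 genes, the real one, and the highest of the others called 12. The gene count thus stood out, but 100 groupings cannot show a share under 1 in 100. The other groupings also mix the labels, which widens the spread within their groups and can lower their counts. Chance is therefore argued against for the gene count but not excluded. For the lists, 54 of the 100 groupings called at least 10, and the highest of the others called 20, so chance cannot be excluded for the count of lists.

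Il6 counts were higher in the libraries labelled knockout. Deeper sequencing is argued against as the cause, because summed counts of the libraries labelled knockout over wild type were 0.9974. An exchange of the group labels cannot be told apart from reads of an interrupted, still transcribed gene, because the genotype label follows the groups. Continued transcription would give a ratio such as 7.33 only if the interrupted gene gave more reads than the intact one, which was not tested. Counts of single exons, not analysed here, could part an exchange of labels from such reads.

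Processed pseudogenes were called in 4.28% of 1051 tested, against 1.9% of other genes, and 41 of the 45 called were lower. A lower yield of the class as a whole is argued against, because its median log2 fold change was 0.1235 (bootstrap interval 0.1011 to 0.1542). Reads shared between a copy and its parent may account for part of it, since parents of the 41 had a median log2 fold change of 0.2032, against 0.0582 for the parents of 941 that were not called (one-sided permutation p = 1e-05, the smallest that 100000 resamples give). Several copies share a parent and all were measured in the same libraries. The permutation treated them as independent, so this p overstates the evidence. Of the 35 distinct parents 6 were called higher, such as Rplp0 (copy Gm8730) and Rps3a1 (copy Rps3a3), and 2 were called lower, Glo1 and Tuba1c, which goes against such sharing for their copies, and the summed change of the 41 copies was -245.4 CPM while that of the parents was 410.4 CPM. Sequence differences between the strains behind the groups, which would move such reads from copy to parent, were not tested and stay open.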
